A study of Mus musculus with 4 samples.

How the data were processed

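RNA sequencing of 4 libraries of cultured mouse cells was used, 2 treated with DMSO and 2 with daidzein, grouped by the titles and treatment labels. Per the labels' protocols the cells grew in alpha-modified minimum essential medium with serum, leukemia inhibitory factor, glial cell line-derived neurotrophic factor, basic fibroblast growth factor and epidermal growth factor, total RNA was extracted with Trizol, and libraries followed standard Illumina protocols. Dose and duration of the daidzein treatment and the strand setting of the counting are not given in the sources used here.

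The submitters' processing notes name HISAT2 2.0.1, HTSeq 0.6.1, DESeq2 and the build mm9, with no role or order. The coordinates in the deposited table are those of GRCm38. Of 55401 genes in the table, 55141 matched the GENCODE M21 annotation of GRCm38 by identifier, and 99.61% of these had the same start. Coordinates are therefore given on GRCm38, as the deposited table lists them.

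The deposited table holds whole-number read counts per gene, which are not normalized, as the values show. It also holds FPKM values by the authors. For 100% of the 65326 FPKM values with a read, the value lay within 0.01 of the count divided by gene length and by the library's total count, on the FPKM scale. Counts were used for all main tests and FPKM for an alternative only. Reads that match several places can be missing or split, so counts of mitochondrial genes with nuclear copies and of genes with many pseudogenes, such as Gapdh, are uncertain. Overlapping antisense genes cannot be told apart without the strand setting. A symbol on several rows, as for 107 symbols, was taken from the row with the most reads.

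Library totals ranged from 16230400 to 18537134, and 19575 genes had a read in any library. The gene with the most reads, Eef1a1, took 1.24% to 1.30% of counts. A floor of 3 counts was used for 0 reads, and 95% intervals and floors cover counting error only where they come from counts of a single gene. Pairs of libraries were compared by chi-square over genes with at least 40 pooled reads. The statistic per degree of freedom ran from 2.18 to 4.60, so all 6 pairs differed by more than sampling noise and none was treated as a duplicate.

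Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test after TMM normalization and the default filterByExpr filter, at a Benjamini-Hochberg adjusted p of 0.05 with no fold threshold. Intervals of folds are 95% intervals from that fit. Values given as CPM with an SD are normalized by TMM. Lists of genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2, for lists with at least 5 tested genes. Of 41 lists, 32 were tested. Terms came from the gene ontology columns of the deposited table and were tested by a one-sided Fisher exact test on terms of 10 to 500 tested genes against 10032 tested genes with any term.

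The tests, lists and alternatives were fixed before the data were examined. Genes named in the text are Clec11a and Itga11, the genes past the threshold with at least 1 FPKM and groups that do not overlap (up to 12 per direction), up to 4 members of each list described with the smallest p plus at most 2 well-known members, and Akt1, Akt2, Mki67, Pcna, Ccnd1, Ddx4, Ifitm3, Pou5f1, Esr1 and Esr2. The result of 1 gene that the rule names is not reported here. Other names were chosen after their values were seen. A further set of blood lineage lists was written after the most abundant and lowest-p genes had been seen.

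The steps were tested on simulated data drawn from the real means, dispersions and library sizes, with 200 of 11700 genes changed. For the comparison of daidzein with DMSO the test recovered 46% of genes changed 1.3-fold, 68% at 1.5-fold, 86% at 2-fold and 98% at 4-fold, with 8 false calls, and 0 calls when no gene was changed. These simulated genes vary independently, which real genes of a pathway do not. They also follow the trend of the dispersions, with no difference between replicate numbers. With 200 genes changed at once the adjusted threshold is easier to pass than with few. The test may therefore recover less in the real data than these shares. Alternatives tried were DESeq2 1.42.0, no filter and a stricter filter of 5 CPM, a prior count of 0.5, the replicate number as a block, robust estimation, each library left out, limma trend on FPKM, an estimated correlation and fry. Removal of trends on gene length and on GC content was added after seeing the data, with a GC value for 99.9% of tested genes. Near-identical copies of germline genes were searched with blastn 2.17.0 at 95% identity over a share of at least 0.5 of the transcript.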

Results

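Gene expression was measured by RNA sequencing in mouse cells that the labels describe as female germline stem cells, a cultured cell type from the ovary of C57BL/6 mice. The cultures received either the solvent DMSO or daidzein, a soy isoflavone that can bind oestrogen receptors. There were 4 libraries, 2 per group. The title of the series concerns the Akt pathway, proliferation and Clec11a, and the comparison asks which transcripts differ with daidzein. The deposited counts summed to 16230400 in DMSO replicate 1, 17119625 in DMSO replicate 2, 17192077 in daidzein replicate 1 and 18537134 in daidzein replicate 2. A gene with 0 reads in a library of this size could have had up to 3 counts, which is 0.162 to 0.185 CPM (counts scaled to the library total). The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

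Most listed transcripts of germline cells were near 0 in both groups, while transcripts of blood cells were abundant in both. Ddx4, an RNA helicase of germ cells, had 2 reads in DMSO replicate 1 and 0 in the other libraries. Pou5f1, a pluripotency factor, had 0 reads in every library, which allows up to 0.0434 CPM over the 4 libraries together. Ifitm3 had 4 reads in DMSO replicate 1, 1 in daidzein replicate 1 and 0 in the others. Of the 30 germline genes listed before the data were examined, 15 had 0 reads in all 4 libraries and 21 had at most 3 reads in total. Kit, a receptor of germ cells and of several blood lineages, was the most abundant gene of the list, with 10574 and 11263 reads in the DMSO libraries and 10620 and 12205 in the daidzein libraries, and Etv5 had 931 to 1123 reads per library. Among the listed immune genes, Ptprc, the pan-leukocyte antigen CD45, stood at 163 ± 3.86 CPM with DMSO and 167 ± 6.22 with daidzein (SD, n = 2 each). Adgre1 stood at 131 ± 0.410 and 122 ± 5.80 CPM. Csf1r had at most 2 reads per library and Cd3e had 0. The fibroblast gene Col1a1 had 2 reads in daidzein replicate 1 and 0 in the other libraries. Kit, Ptprc and Adgre1 did not pass edgeR's test between the groups, each with an adjusted p of 1.00, and every comparison that follows is between libraries with this make-up.

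**Figure D1:**
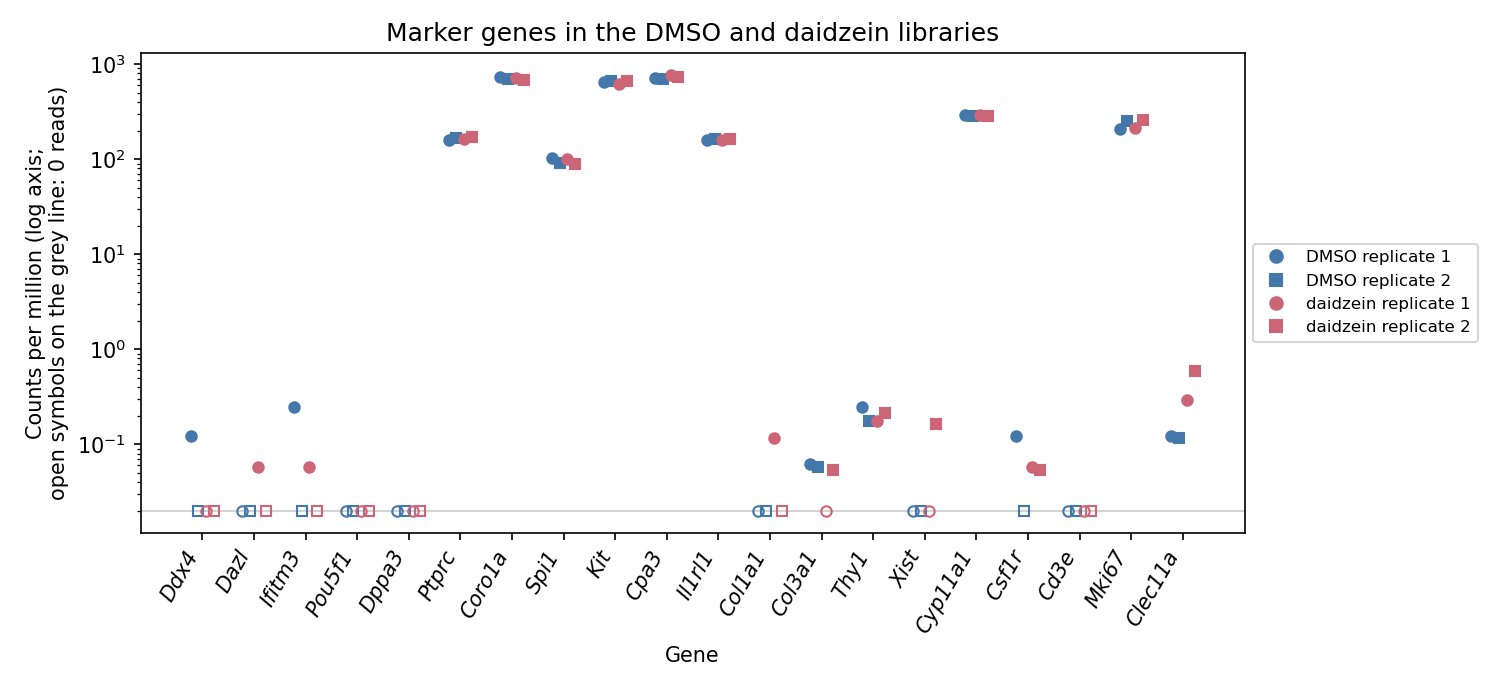
CPM of marker genes (x axis) in each of the 4 libraries on a log axis, with open symbols on the grey line for 0 reads. Ptprc lies between 160 and 172 CPM in all 4 libraries and Ddx4 at 0 in 3 of them; the genes shown were chosen after the values were seen, apart from those fixed in lists.

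Without the replicate number in the fit, daidzein and DMSO libraries differed in 2 genes, Fos and Fosb. They encode subunits of the AP-1 transcription factor and are induced within minutes of a stimulus. Both fell with daidzein. Fos (ENSMUSG00000021250; GRCm38 chromosome 12, 85473890 to 85477273, plus strand) went from 54.7 ± 12.6 to 29.6 ± 2.24 CPM (SD, n = 2 each), a fold of 0.542 with a 95% interval of 0.457 to 0.643. Fosb (ENSMUSG00000003545; GRCm38 chromosome 7, 19302696 to 19310051, minus strand) went from 17.1 ± 4.98 to 7.23 ± 1.70 CPM (SD, n = 2 each), a fold of 0.426 with an interval of 0.325 to 0.560. Both are annotated as protein-coding genes, and in both the DMSO libraries lay above the daidzein libraries. Adjusted p was 0.00551 for Fos and 0.0177 for Fosb in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 11700 genes tested, 0 rose and 2 fell, and only Fosb fell by at least 2-fold. The same fit also called 2 genes for a crossed split, DMSO replicate 1 with daidzein replicate 2 against the other libraries. The count of 2 by itself therefore does not exceed that of a grouping without treatment. At an unadjusted p under 0.05 there were 341 genes, 151 higher and 190 lower with daidzein, where chance alone gives 585. DESeq2 also called 0 rises and 2 falls, both of them Fos and Fosb. A limma trend test on log2(FPKM + 1) called 0 genes, with 379 at an unadjusted p under 0.05, an adjusted p of 0.450 for Fos and 0.787 for Fosb. With a stricter filter Fosb had an adjusted p of 0.0692 by edgeR. Leaving out 1 library gave 4 genes without DMSO replicate 1, 12 without DMSO replicate 2, 11 without daidzein replicate 1 and 17 without daidzein replicate 2, with Fos and Fosb among them each time.

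**Figure D2:**
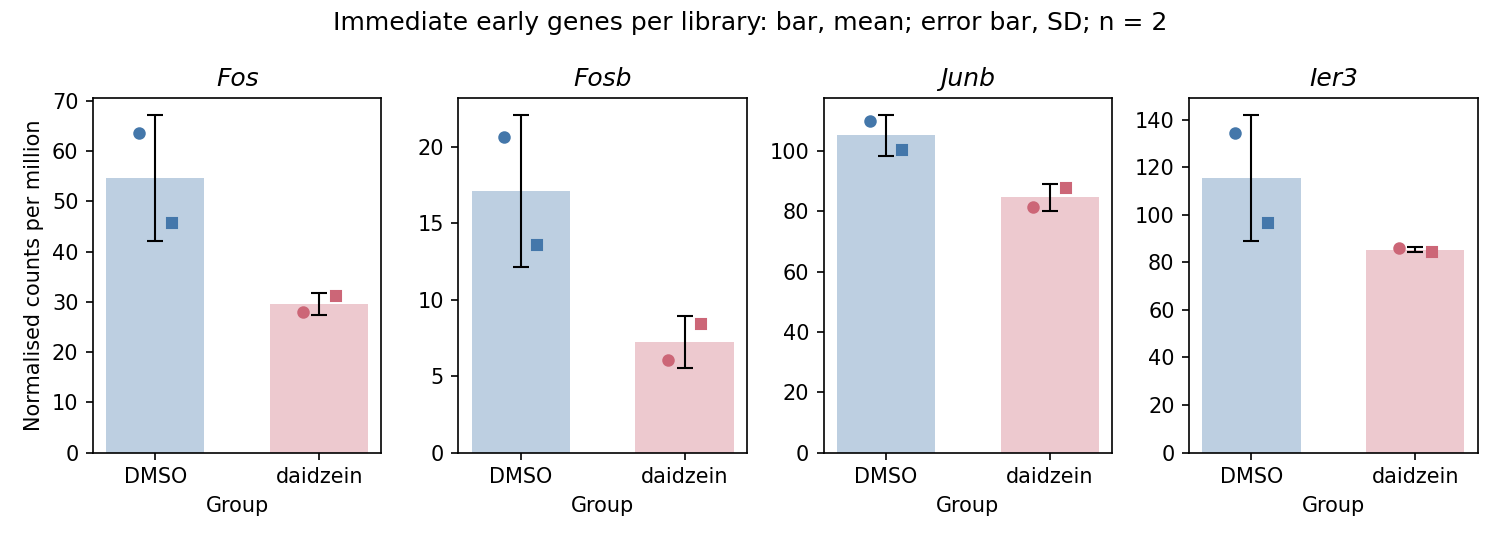
Normalised CPM (y axis, from 0) of Fos, Fosb, Junb and Ier3 in the DMSO and daidzein groups. Bars are means, error bars SD of n = 2, circles replicate 1 and squares replicate 2; for Fos the DMSO libraries are at 63.6 and 45.8 and the daidzein libraries at 28.0 and 31.1.

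Immediate early genes, which respond rapidly to growth signals and stress, were lower as a group with daidzein. Of 19 tested, 15 were lower and 4 higher, 2 fell after adjustment over all genes, and 6 fell when adjusted over the list alone. Besides Fos and Fosb, Junb had a fold of 0.805 (95% interval 0.727 to 0.891), Ier3 of 0.739 (0.638 to 0.856) and the growth-response factor Egr1 of 0.794 (0.688 to 0.917). The log2 difference of Ier3, -0.44, was -0.18 without DMSO replicate 1 and -0.65 without DMSO replicate 2. Over all genes Ier3 and Junb did not pass in the main edgeR fit, with an adjusted p of 0.628 each, or by DESeq2, with 0.999 each. The stricter filter, robust estimation and limma trend on FPKM did not call them either. Without a filter on low counts they passed by edgeR, with an adjusted p of 1.08e-05 for Ier3 and 0.0438 for Junb. That fit also moved Fos from an adjusted p of 0.00551 to 5.21e-17, so its values are not on the scale of the main fit. With the replicate number as a block Ier3 and Junb passed too, with an edgeR adjusted p of 0.000825 and 0.00493. Jun had a fold of 0.882 with an interval of 0.711 to 1.09. The median log2 difference of the list was -0.18, with an adjusted p of 0.000144 by camera with a preset correlation. The adjusted p was 0.944 with an estimated correlation, 0.573 by fry and 0.227 by camera without DMSO replicate 1.

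Genes encoded in the mitochondrial genome, which specify subunits of the respiratory chain, were slightly higher with daidzein. Of 12 tested, 11 were higher, 0 rose after adjustment over all genes, and 8 rose when adjusted over the list alone. The median log2 difference was 0.18. mt-Nd2 had a fold of 1.15 (95% interval 1.06 to 1.25), mt-Cytb of 1.11 (1.03 to 1.20) and mt-Co1 of 1.05 (0.971 to 1.14). The log2 difference of mt-Nd2, 0.20, was 0.13 without DMSO replicate 1. The log2 difference of mt-Nd6, 0.25, was 0.19 without DMSO replicate 1 and 0.31 without DMSO replicate 2. Without a filter on low counts mt-Nd2 and mt-Nd6 passed over all genes by edgeR, with an adjusted p of 0.0140 and 0.0495. DESeq2, over the same 19575 genes, gave both an adjusted p of 0.999, so these calls depend on the method. The unfiltered edgeR fit is not on the scale of the main fit, as Fos shows above. mt-Co2 had a fold of 1.29 and mt-Atp6 of 1.51, but both share sequence with nuclear copies and their counts are uncertain. mt-Co3, mt-Nd3 and mt-Atp8 had at most 228, 27 and 18 reads per library, against at least 91425 for mt-Co1. The intervals of their folds include 1, so their directions are uncertain too. mt-Nd6 had a fold of 1.19 and lies on the strand opposite to its neighbours, so without known strand handling its reads may belong to them. Mitochondrial genes took 1.57% and 1.73% of counts with DMSO and 1.80% and 1.81% with daidzein. The nuclear-encoded respiratory chain list had 16 genes higher and 16 lower among 32, with a camera adjusted p of 0.918. The camera adjusted p of the mitochondrially encoded list was 1.89e-06, against an adjusted p of 0.944 with an estimated correlation and 0.569 by fry. By camera it was 0.0494 without DMSO replicate 1 and 0.00274 without daidzein replicate 1. Over all tested genes the difference between daidzein and DMSO had a Spearman correlation of -0.21 with GC content. With a trend on GC content removed, the list median was 0.10 and its camera adjusted p 0.000395.

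**Figure D3:**
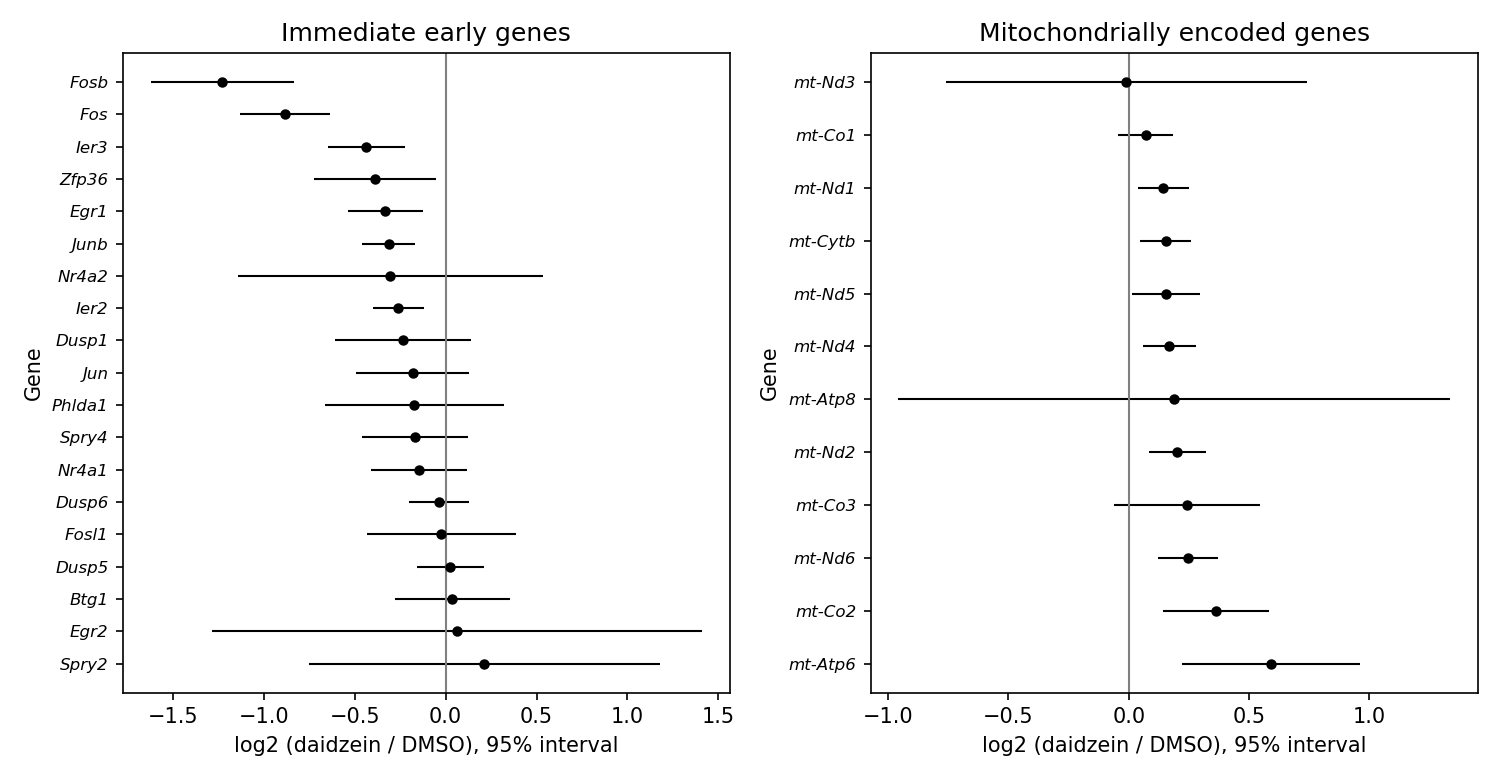
Log2 difference between daidzein and DMSO (x axis) for each tested gene of the immediate early list and of the mitochondrially encoded list (y axis), with 95% intervals of the edgeR fit. Fosb at -1.23 and Fos at -0.88 lie farthest from 0 in the immediate early panel, and 11 of 12 mitochondrial genes lie above 0.

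Of 18 listed genes of the Notch pathway, a cell-contact signalling route, 8 had enough reads to test and all 8 were lower. Those not tested include 5 with 0 reads in every library, so a change of the whole pathway was not tested. Folds of the 8 ran from 0.658 for Hey1, at 23 to 40 reads per library, to 0.978 for Rbpj. The ligand gene Jag2 had a fold of 0.820 (95% interval 0.720 to 0.935) and was the 1 gene that fell when adjusted over the list alone, while 0 fell over all genes. The receptor gene Notch1 had a fold of 0.895 (0.756 to 1.06) and the target gene Hey1 of 0.658 (0.399 to 1.08). The log2 difference of Hey1, -0.60, was -0.34 without DMSO replicate 2. The median log2 difference was -0.16, with a camera adjusted p of 0.00503, an adjusted p of 0.944 with an estimated correlation and 0.501 by fry. By camera the adjusted p was 0.231 without a filter on low counts, and it was 0.188 without DMSO replicate 1, 0.0713 without DMSO replicate 2, 0.0878 without daidzein replicate 1 and 0.470 without daidzein replicate 2. In all, 3 of 32 lists tested passed with the preset correlation and 0 passed with an estimated correlation or by fry. With the estimated correlation 0 of 32 had even an unadjusted camera p under 0.05, so that version could hardly single out any list. The calls of the 3 lists therefore rest on the preset correlation alone.

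Clec11a, which encodes a secreted C-type lectin growth factor and is named in the title of the series, was barely detected in either group. Clec11a (ENSMUSG00000004473; GRCm38 chromosome 7, 44302687 to 44306902, minus strand) had 2 and 2 reads in the DMSO libraries and 5 and 11 in the daidzein libraries. This is 0.120 CPM with DMSO and 0.448 CPM with daidzein, pooled over the libraries of a group. The ratio per depth was 3.73, with a 95% exact binomial interval of 1.20 to 15.3 that covers counting error only. It was 2.42 without daidzein replicate 2. The gene was below the filter on low counts and so was not among the genes tested. With that filter taken off, edgeR gave a fold of 3.56 and an adjusted p of 0.976, with an unadjusted p of 0.0704, and DESeq2 gave a fold of 3.69 and an adjusted p of 0.999. Itga11 (ENSMUSG00000032243), an integrin subunit known as a receptor for the Clec11a protein, had 1 read in DMSO replicate 1 and 0 in the other libraries. A difference in Itga11 was not detectable at this depth.

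Transcripts of the PI3K and Akt pathway differed little between the groups, as did those of the cell cycle. Akt1 had a fold of 0.991 (95% interval 0.914 to 1.07) and Akt2 of 1.00 (0.917 to 1.09). Of 35 pathway genes tested, 17 were higher and 18 lower with daidzein, and 0 rose or fell over all genes or adjusted over the list alone by edgeR. Rps6kb1, which encodes the S6 kinase, had the smallest p of the list, with a fold of 1.09, and its log2 difference, 0.13, was 0.02 without DMSO replicate 1 and 0.25 without DMSO replicate 2. The camera adjusted p of the pathway list was 0.918, and its median and mean log2 differences had opposite signs, -0.01 and 0.0031. Mki67, a marker of proliferating cells, had a fold of 1.03 (0.915 to 1.16), Pcna of 0.992 (0.921 to 1.07) and the cyclin gene Ccnd1 of 0.979 (0.892 to 1.07). Of 40 cell cycle genes tested, 15 were higher and 25 lower, 0 rose or fell over all genes or adjusted over the list alone, and the camera adjusted p was 0.878. Of 6 genes tested in the list of G1 cyclins, their kinases and Myc, 3 were higher and 3 lower, with a camera adjusted p of 0.939. With 1 library left out at a time, Akt1, Akt2, Mki67, Pcna and Ccnd1 each changed direction at least once, with log2 differences between -0.09 and 0.19. Transcript counts do not measure Akt phosphorylation or cell division.

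The oestrogen response genes with enough reads to test did not pass the list test. Esr1, the gene of oestrogen receptor alpha, was low, at 2.63 ± 0.481 CPM with DMSO and 3.63 ± 0.254 with daidzein (SD, n = 2 each), a fold of 1.38 (95% interval 0.958 to 1.98). Its log2 difference, 0.46, was 0.29 without DMSO replicate 1. Esr2, the gene of oestrogen receptor beta, had 1 read in daidzein replicate 2 and 0 elsewhere. Of 21 listed oestrogen response genes, 10 had enough reads to test. Among these, 4 were higher and 6 lower, with a camera adjusted p of 0.933. Those not tested include 4 with 0 reads in every library, so a response of the whole pathway was not tested. Of 27 hypoxia and glycolysis genes tested, 22 were lower and 5 higher, with a camera adjusted p of 0.0744. By camera the adjusted p was 0.0400 with the replicate number as a block and 0.383 without a filter on low counts. The adjusted p of this list was 0.944 with an estimated correlation and 0.573 by fry. Hk2, the gene of hexokinase 2, had a fold of 0.877 (0.800 to 0.961) and did not pass over all genes. Of 6 germline genes with enough reads to test, 2 were higher and 4 lower, with a camera adjusted p of 0.768. Among 1624 annotation terms, 6 were over-represented among the genes that fell by a one-sided Fisher exact test, and all of them rest on Fos and Fosb alone. They include response to cAMP and cellular response to calcium ion. No term could be tested for genes that rose, since 0 rose by edgeR.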

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

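Alternatives were fixed before the data were examined, except the removal of length and GC trends, which was chosen after seeing the data. By edgeR the count of changed genes, 2, was 11 without a filter on low counts, 1 with the stricter filter and 0 by limma trend on FPKM. It ran from 4 to 17 with a library left out, where the lone library of a group is assumed to vary like the others. It was 2 by DESeq2, with robust estimation and with length or GC trends removed, and both Fos and Fosb were among the genes called in every setting that called at least 2. With the replicate number as a block it was 27, of which 6 rose and 21 fell, with 748 genes at an unadjusted p under 0.05. Junb, Ier3, mt-Nd6 and mt-Nd2 then passed, with edgeR adjusted p of 0.00493, 0.000825, 0.00420 and 0.00420. These genes also passed by edgeR without the filter, but not by DESeq2, with an adjusted p of 0.999 each. The hypoxia and glycolysis list passed with the block too, with a camera adjusted p of 0.0400. No label used here gives same-numbered samples a shared batch or culture, so the numbers were not taken to pair them. Same-numbered deviations had a correlation of 0.09 over genes, in only 2 pairs. By chi-square per degree of freedom, however, same-numbered libraries were closer, at 3.4 and 2.2, than those of 1 group, at 4.0 and 4.2. Splitting the libraries by number called 53 genes, with 1614 at an unadjusted p under 0.05 by edgeR, where chance alone gives 585. Same-numbered libraries therefore share a difference, of unknown source, and the count of 2 without a block may be too low. The count of lists, 3, was 0 with an estimated correlation and 0 by fry, ran from 1 to 4 with a library left out, and was 4 with the replicate block. The Clec11a ratio, 3.73, ran from 2.42 to 4.95 with a library left out and was 3.73 with the replicate block. All were above 1 and within its counting interval. With reads of 2 and 2 against 5 and 11 they could hardly be otherwise, so this adds no support. The 6 annotation terms became 0 when calls also needed a 2-fold change, since only 1 gene was left. Of 519 recomputed values of 44 genes, 503 stayed on their side of the threshold, 13 passed it and 3 no longer did. Only Fos and Fosb had a call to lose, and most of the 503 values belong to genes not among the 2 called. Of values past the threshold before or after, 0 changed direction, while some that never passed did. The cause of the other changes was not tested. For Clec11a the stricter filter gave no value and robust estimation was not run. Pseudocounts for FPKM were not run, since counts were used, and robust estimation does not apply to camera.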

Other observations

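The tests of germline reads and of blood lineages were chosen after the results were seen, and the lineage lists were written after the most abundant genes had been seen. How a tie of lineage shares and a count near its bound were judged was also set after those values were seen. All 15 listed transcripts shared by most blood cells were at 10 CPM or more over the 4 libraries pooled, among them Coro1a at 707 CPM, Arhgdib at 665 CPM and the transcription factor Spi1 at 95.7 CPM. Cpa3, a mast cell protease, stood at 730 CPM, Il1rl1, the receptor of interleukin 33, at 161 CPM, and Itga2b, an integrin of platelets and blood progenitors, at 215 CPM. Several transcripts of mature mast cells were not detected, with 0 reads for Mcpt4, Tpsb2 and Fcer1a. Cyp11a1, which starts steroid synthesis, stood at 289 CPM, while the granulosa genes Foxl2 and Fshr had 0 reads. Of the lineage lists, 6 of 18 mast cell genes, 3 of 9 red cell and platelet genes and 1 of 8 macrophage genes reached 10 CPM, against 0 of 8 T cell, 0 of 7 B cell, 0 of 8 neutrophil and 0 of 4 basophil genes. Xist, the transcript of the inactive X chromosome, had 3 reads in daidzein replicate 2 and 0 in the other libraries, and the 4 Y-linked genes had 1 read in total.

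Germline markers near 0 beside abundant blood cell transcripts may have several sources. A minority of blood cells in a germline culture would not account for a median of 0.5 pooled reads over the germline list. That median is part of the pattern itself, so it is not a separate test. Loss of reads to near-identical copies is argued against, since such a copy among annotated transcripts was found for 1 of 30 germline genes. The others had a median of 1 pooled read, which leaving out 1 gene could barely move. Cells of the mast cell lineage were expected to have the largest share of listed genes at 10 CPM or more, and this was not met, since 33.3% of the mast cell list and 33.3% of the red cell and platelet list reached it, so the lineage stays open. A hypothesis that these libraries come from blood-lineage cells, or from samples other than those labelled, was not tested against any outside sample.

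The lower immediate early genes in the daidzein libraries could be an effect of daidzein, which stays open. A gene length trend is argued against, since with it removed the list median was -0.17, and a GC trend likewise, at -0.16. Differences between libraries within a group cannot be told apart from the treatment, since 4 libraries make only 3 splits. Of these, 1, the real one, had a camera p as small as 8.97e-06, and the smallest other was 0.00247. By edgeR the real split and the crossed split each called 2 genes. How the cultures were handled before RNA extraction, to which these genes respond, was not tested.

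Libraries numbered 1 and 2 differed in both groups: splitting the 4 libraries by number called 53 genes, against 2 by treatment and 2 by the remaining, crossed split, and 251 genes with treatment in the model, of which 178 were higher in number 2, with a median length of 11069 bases against 1716 for those lower. With a length trend removed, 133 genes differed by number, 75 of them among the 251. The count of 133 is above the bound of 125.5 set beforehand for length as the main source, so that prediction was not met. Yet the 75 that stayed called are below the bound, and the rest of the 133 were new calls. Length therefore cannot be told apart from other sources. With a GC trend removed, 333 genes differed, 177 of them among the 251. Both counts are above the bound, which argues against GC content as the main source. A structure of the samples such as RNA quality or library preparation may lie behind the split, and no biological explanation was tested.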
